A study of Homo sapiens with 4 samples.

How the data were processed

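RNA from HMT-S1 cells was measured by sequencing of polyadenylated RNA in 4 samples, 2 transfected with an empty vector and 2 with 4SA-TAZ. Per the labels' protocols, transfected cells were kept as a population after 4 days of puromycin, and libraries were made with a strand-marking poly(A) kit from 250 ng of total RNA with inserts of 300 bp. Paired reads of 150 nt were then sequenced on an Illumina instrument, per the labels' protocols. The sample descriptions in the labels place both vector libraries on lane 7 and both 4SA-TAZ libraries on lane 8, so lane and group cannot be told apart and no within-lane value could be computed. The labels call the samples replicates but do not say that they came from separate cultures or transfections. All p-values therefore measure only the spread between these samples, which may be technical.

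The authors deposited a table of whole-number counts per Ensembl gene with one column per sample and no normalization. Per the submitters' processing notes, TopHat2 2.1.1, SAMtools 1.4.1 and featureCounts 1.5.3 were used, and the builds GRCh38, hg19 and hg38 are named without a role for each. The annotation, the strand setting of the counting and the treatment of reads that align to several places are not given in the sources used here. Counts of genes with close relatives, such as ALPG, ANKRD30B, the HLA genes, the keratins, SAA1 and the PSG genes, are therefore uncertain to the extent that reads were split or dropped between copies. Counts of genes that overlap another gene or have an antisense partner carry the same doubt. The counts of the 13 mitochondrially encoded genes were 0 in all 4 libraries, so the share of mitochondrial reads could not be used as a measure of RNA quality.

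Gene symbols came from a gene name table, in which 57392 of the 58233 gene IDs were found, and coordinates from GENCODE 29 on GRCh38, in which 57895 were found. Coordinates printed here are those of that annotation and not of the deposited table. The total count per library was 20171187 and 12437337 for vector replicates 1 and 2, and 15584298 and 8991524 for 4SA-TAZ replicates 1 and 2. A count of 0 was read as an upper limit of 3 counts, which corresponds to between 0.149 and 0.334 per 1000000 counts in single libraries. Where both libraries of a group had 0 counts, the fold is a lower bound computed against 3 counts over the group. Such limits cover counting error only.

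Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood test, after filtering by its default expression filter and TMM normalization, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The design had group as its only term and left 2 residual degrees of freedom. Standard errors of log2 fold changes were derived from the test's F statistic, and fitted fold changes used a prior count of 0.125. Normalised counts are given per 1000000 counts of the TMM-scaled library size (CPM), as mean ± SD over the 2 libraries of a group. Gene lists were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 22 lists with at least 5 tested members. The same lists were tested with an estimated correlation and with fry, which asks whether a list moves on balance in one direction without comparing it with other genes. With an estimated correlation camera also takes its p-values from the 2 residual degrees of freedom, so few lists can pass. A failure there does not by itself show that correlation between genes undoes a call.

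Before the data were examined, 24 lists were fixed: 18 on biology, 3 of markers of other cell types and 3 on RNA quality. The rule for named genes was fixed at the same time. WWTR1 and YAP1 were always named. Among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the groups, the 8 largest increases and the 8 largest decreases with a gene symbol were named, leaving out LOC, antisense, pseudogene and readthrough names. For each list on biology the 3 tested members with the smallest unadjusted p were named, and for each other list the 1 member with the highest mean CPM. List members that did not pass the test are given with values only, and a gene that the rule names among the luminal markers is not reported here. Genes outside this rule that are named were chosen after their values were seen, and are said to be so.

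The following alternatives were planned: size factors from DESeq2, library size only and upper quartile scaling, no filter and a filter of 1 CPM, the Wald test of DESeq2 1.42.0, limma-voom, robust dispersion shrinkage, a test of change over 1.5-fold, counts thinned to the smallest library, the replicate number as a block, and each library left out in turn. Leaving out the genes of chromosome 6 and leaving out gene models within ribosomal RNA loci were added after the data were examined. Their effect is given in the closing section.

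The scripts were tested on simulated data drawn from the means and library sizes of these samples, with 50 genes changed at each fold among 13585 genes run. The test recovered 0 of 50 genes changed 1.5-fold, 4 of 50 changed 2-fold, 39 of 50 changed 4-fold and 47 of 50 changed 8-fold, and called 12 of 13385 unchanged genes. With no changed gene it called 0 genes. Both simulated groups had the same spread per gene, whereas the vector duplicates of these data differed more than the 4SA-TAZ duplicates. Figures were drawn with matplotlib 3.10.9. Levels of genes linked to sex were not analysed here.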

Results

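The data were counts per gene from sequencing of polyadenylated RNA of HMT-S1 cells, an epithelial-like, non-tumorigenic human mammary line. The cells had been transfected with an empty vector or with 4SA-TAZ, and the question was what expression of activated TAZ changes in mammary epithelial cells. TAZ, encoded by WWTR1, is a transcriptional co-activator that the Hippo pathway kinases restrain by phosphorylation, and 4SA-TAZ is a form that lacks serines they phosphorylate. Each group held 2 libraries, and their totals ranged from 8991524 to 20171187 counts. Of 58233 genes in the table, 31563 had no count in any library and 13904 passed the expression filter and were tested.

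WWTR1 (ENSG00000018408, chromosome 3, 149517235 to 149736714 on GRCh38, protein coding) had 107 and 166 CPM in vector replicates 1 and 2 and 270 and 235 CPM in 4SA-TAZ replicates 1 and 2. Both 4SA-TAZ libraries lay above both vector libraries, with a log2 fold change of 0.89 ± 0.26 (SE, n = 2 per group), which did not pass the threshold (adjusted p = 0.071, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The call changed with the filter and the test used. By the same edgeR test the adjusted p was 0.00203 with no filter and 0.0716 with the filter of 1 CPM. It was 0.0247 with the Wald test of DESeq2 and 0.064 with limma-voom. With a library left out the log2 fold change ranged from 0.61 (without vector replicate 1) to 1.23 (without vector replicate 2). Those fits took their spread from the other group alone, so their p-values are not given for WWTR1. Counts on this gene model sum the cell's own transcript and whatever part of the introduced sequence aligned to it, and the introduced sequence is not given in the sources used here. YAP1, the paralog of WWTR1 (ENSG00000137693, chromosome 11, 102110461 to 102233423), fell 2.24-fold, from 265 ± 9.03 to 118 ± 4.89 CPM (SD, n = 2), with an adjusted p of 0.00841 by the same edgeR test. Without 4SA-TAZ replicate 1 or 2 YAP1 fell 2.2-fold or 2.28-fold. It did not pass there, with the spread taken from the vector libraries alone.

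Between vector and 4SA-TAZ, 2617 of the 13904 tested genes changed, of which 1177 were higher and 1440 lower in 4SA-TAZ (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 1023 rose and 1325 fell more than 2-fold. By fitted fold change, which places genes at 0 counts high, the largest increases were in genes with 0 counts in both vector libraries. MME, which encodes the membrane peptidase neprilysin, reached 75.6 ± 2.26 CPM in 4SA-TAZ (SD, n = 2), at least 835-fold higher. ANKRD30B was at least 788-fold, the lipoprotein receptor gene OLR1 at least 772-fold, ZNF804A at least 480-fold and the non-coding LINC01224 at least 479-fold higher. KISS1, which encodes the kisspeptin precursor, was at least 396-fold higher, the alkaline phosphatase gene ALPG at least 357-fold and the semaphorin gene SEMA3D at least 338-fold. By the same ranking the largest decreases were in genes with 0 counts in both 4SA-TAZ libraries. TP63, a master regulator of basal epithelial identity (ENSG00000073282, chromosome 3, 189631416 to 189897279), had 72.5 ± 17 CPM in vector (SD, n = 2) and was at least 587-fold lower. The epsin gene EPN3 was at least 1058-fold and CLCA2 at least 998-fold lower. Bounds for POSTN (periostin), the receptor phosphatase gene PTPRZ1, PNLIPRP3, STON2 and the urate transporter gene SLC2A9 were at least 561-fold, 480-fold, 333-fold, 321-fold and 235-fold lower. PNLIPRP3 had 62.2 and 20.2 CPM in vector replicates 1 and 2, and its bound was 163-fold without vector replicate 1 and 503-fold without vector replicate 2. With 1 library of the group at 0 left out, the limit rests on the other library alone. Bounds of the 8 increases then lay between 126-fold and 311-fold without vector replicate 1 and between 212-fold and 524-fold without vector replicate 2. Bounds of the 8 decreases lay between 84.7-fold and 382-fold without 4SA-TAZ replicate 1 and between 150-fold and 676-fold without 4SA-TAZ replicate 2. All 16 of these genes had adjusted p between 4.5e-04 and 0.00642 by edgeR's quasi-likelihood test. The bounds do not follow the ranking, and genes with a few counts in the lower group can exceed them. COL17A1, with 6 and 4 counts in 4SA-TAZ, had a fitted fall of 1733-fold. FBN2, with 0 and 3 counts in vector, had a fitted rise of 1074-fold.

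In 8562 of the tested genes (61.6%) both libraries of one group lay above both of the other, where chance gives 33.3%. The number of changed genes was 6287 without vector replicate 1 and 9029 without vector replicate 2, and 1314 and 1499 without 4SA-TAZ replicate 1 and 2, with the libraries of the other group then giving the spread. Among genes with at least 5 CPM, 1325 of 10628 differed more than 2-fold between the vector duplicates (12.5%), against 10 of 10258 between the 4SA-TAZ duplicates (0.0975%).

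**Figure D1:**
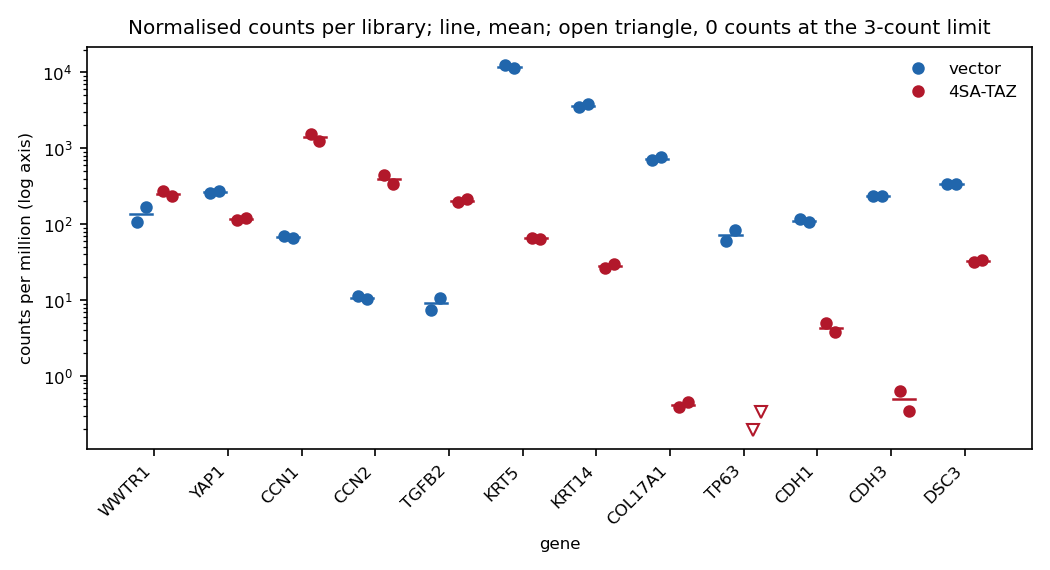
Normalised counts (CPM, log axis) of WWTR1, YAP1 and named target, basal and junction genes in each of the 4 libraries, with a line at the group mean and an open triangle at the 3-count limit where a library had 0 counts. CCN2 had 391 CPM on average in 4SA-TAZ against 10.8 in vector, while KRT5 had 65.3 against 11866.

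The list of YAP/TAZ target genes, transcripts known to be driven by these co-activators, rose as a group. Of its 22 tested members 14 rose, 0 fell and 8 did not pass the test, and 15 rose when adjusted over the list alone. The median log2 fold change was 1.57 (camera, adjusted p = 4.7e-07, and adjusted p = 0.346 with an estimated correlation and 0.00839 with fry). CCN2, a secreted matrix-associated protein gene (ENSG00000118523, chromosome 6, 131948176 to 131951373), rose 36.1-fold, from 10.8 ± 0.631 to 391 ± 66.9 CPM (SD, n = 2, log2 SE 0.24). CCN1 (ENSG00000142871, chromosome 1, 85580761 to 85583962) rose 20.7-fold, from 67.8 ± 3.87 to 1407 ± 200 CPM, and the ligand gene TGFB2 rose 22.6-fold, from 9.13 ± 2.31 to 205 ± 15.2 CPM. Adjusted p was 4.3e-04, 4.7e-04 and 5.9e-04 for CCN2, CCN1 and TGFB2 by edgeR's quasi-likelihood test. ANKRD1, singled out after its values were seen, had 8 and 0 counts in the vector libraries and 3932 and 2381 in the 4SA-TAZ libraries. Of the tested members, 3 lie on chromosome 6, whose genes were higher as a whole, and without that chromosome the list had an adjusted p of 5.3e-06.

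**Figure D2:**
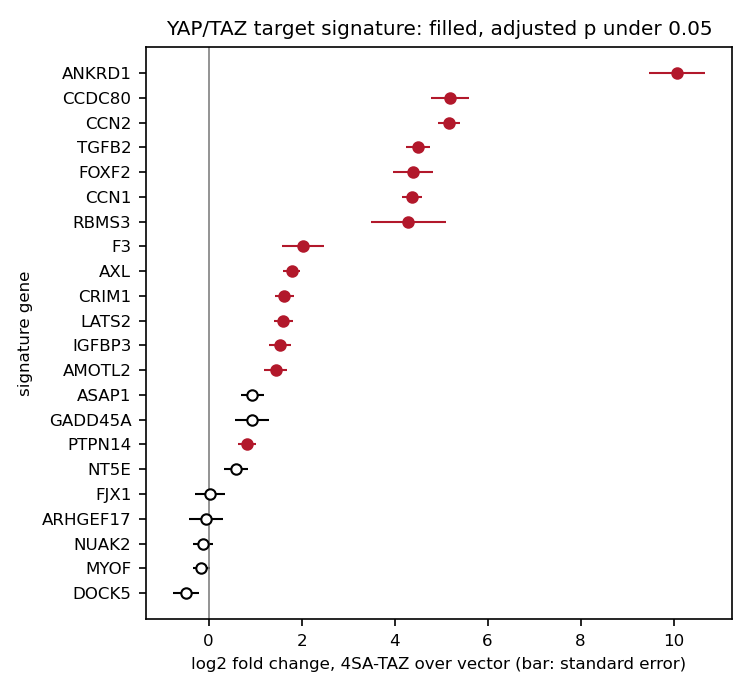
Log2 fold change (4SA-TAZ over vector) with its standard error for each of the 22 tested genes of the YAP/TAZ target signature, filled where the adjusted p was under 0.05. The 14 filled genes all lie above 0.

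Genes of the Hippo pathway itself went both ways. Of 30 tested members 12 rose, 3 fell and 15 did not pass, with 14 and 4 when adjusted over the list alone. The list was not called (camera, adjusted p = 0.0805, or 0.057 with fry), although by camera its adjusted p was 0.00769 with no filter. By camera it also passed without 4SA-TAZ replicate 1 or 2, but not without vector replicate 1 or 2. The TEAD cofactor gene VGLL3 rose 20.4-fold, from 5.98 ± 2.96 to 124 ± 23.1 CPM (SD, n = 2), or 31.7-fold without vector replicate 1, and the scaffold gene WWC2 rose 2.84-fold. AMOTL1, which encodes an angiomotin that binds YAP and TAZ, fell 4.07-fold. AMOTL1 and YAP1 lie between 90000001 and 130000000 on chromosome 11, where the median log2 fold change of the 174 tested genes was -0.43. Adjusted p for VGLL3, WWC2 and AMOTL1 lay between 0.0019 and 0.00378 by edgeR's quasi-likelihood test.

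Epithelial junction and identity genes fell as a group. Of 28 tested members 21 fell, 2 rose and 5 did not pass, also when adjusted over the list alone. The median log2 fold change was -2.91 (camera, adjusted p = 2.1e-09, and adjusted p = 0.346 with an estimated correlation and 0.00839 with fry). E-cadherin, CDH1 (ENSG00000039068, chromosome 16, 68737225 to 68835548), fell 25.1-fold, from 111 ± 7.44 to 4.36 ± 0.846 CPM (SD, n = 2). P-cadherin, CDH3, fell 436-fold from 234 ± 1.82 CPM to 0.493 ± 0.214 CPM, or 674-fold without 4SA-TAZ replicate 1, and the desmosomal cadherin gene DSC3 fell 10.4-fold to 32.6 ± 1.3 CPM. Basal and myoepithelial mammary markers fell with them, 18 of 25 tested members, while 3 rose and 4 did not pass, the same counts as when adjusted over the list alone. Their median log2 fold change was -4.91, also with genes at 0 in a group set to their bounds. Camera gave an adjusted p of 1.2e-08, or 0.346 with an estimated correlation, and fry gave 0.00839. KRT5 (ENSG00000186081, chromosome 12, 52514575 to 52520687), a basal keratin, fell 182-fold, from 11866 ± 775 to 65.3 ± 1.93 CPM (SD, n = 2). KRT14 fell 129-fold from 3649 ± 247 CPM, and the hemidesmosomal collagen gene COL17A1 fell 1733-fold from 732 ± 50.6 CPM to 0.422 ± 0.0494 CPM. Each of CDH1, CDH3, DSC3, KRT5, KRT14 and COL17A1 had an adjusted p between 4.2e-04 and 5.4e-04 by edgeR's quasi-likelihood test. The 3 basal list members that rose, named after their values were seen, were MME, the oxytocin receptor gene OXTR (log2 3.55 ± 0.21, SE) and the myosin light chain kinase gene MYLK (log2 2.30 ± 0.29, SE).

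Luminal mammary markers showed no common direction, with 3 of 13 tested members higher, 4 lower and 6 not passing, over all genes and when adjusted over the list alone (camera, adjusted p = 0.988). The protease inhibitor gene SLPI fell 106-fold, from 54 ± 1.48 CPM (SD, n = 2) to 7 and 5 counts in the 4SA-TAZ libraries. AGR2 fell from 60.5 ± 27.9 CPM to 3 and 0 counts in the 4SA-TAZ libraries.

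Mesenchymal genes likewise divided, with 8 of 23 tested members higher, 6 lower and 9 not passing, and 9 and 7 when adjusted over the list alone. The median log2 fold change was 0.19 and the mean -0.52, or -0.35 with genes at 0 in a group at their bounds (camera, direction up, adjusted p = 0.868). The transcription factor gene ZEB2 rose 10.8-fold to 39.1 ± 1.82 CPM (SD, n = 2), whereas the gelatinase gene MMP2 fell 72-fold from 40.7 ± 0.649 CPM, or 174-fold without 4SA-TAZ replicate 1, and POSTN had 0 counts in 4SA-TAZ. MMP2 had 12 and 2 counts in the 4SA-TAZ libraries. Among collagens and matrix genes 11 of 29 tested members rose, 8 fell and 10 did not pass, with 11 and 9 when adjusted over the list alone (camera, adjusted p = 0.868). FBN1 rose 15-fold, and its relative FBN2, with 0 and 3 counts in the vector libraries, reached 109 ± 15.2 CPM. COL7A1, the collagen of anchoring fibrils, fell 32.5-fold from 380 ± 7.12 CPM. TGF-beta response genes had 7 of 22 higher, 5 lower and 10 not passing, with 7 and 8 when adjusted over the list alone (camera, adjusted p = 0.808). TGFBI fell 40-fold from 305 ± 8.27 CPM, while BMP4 rose 19.8-fold to 88.8 ± 10.6 CPM.

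**Figure D3:**
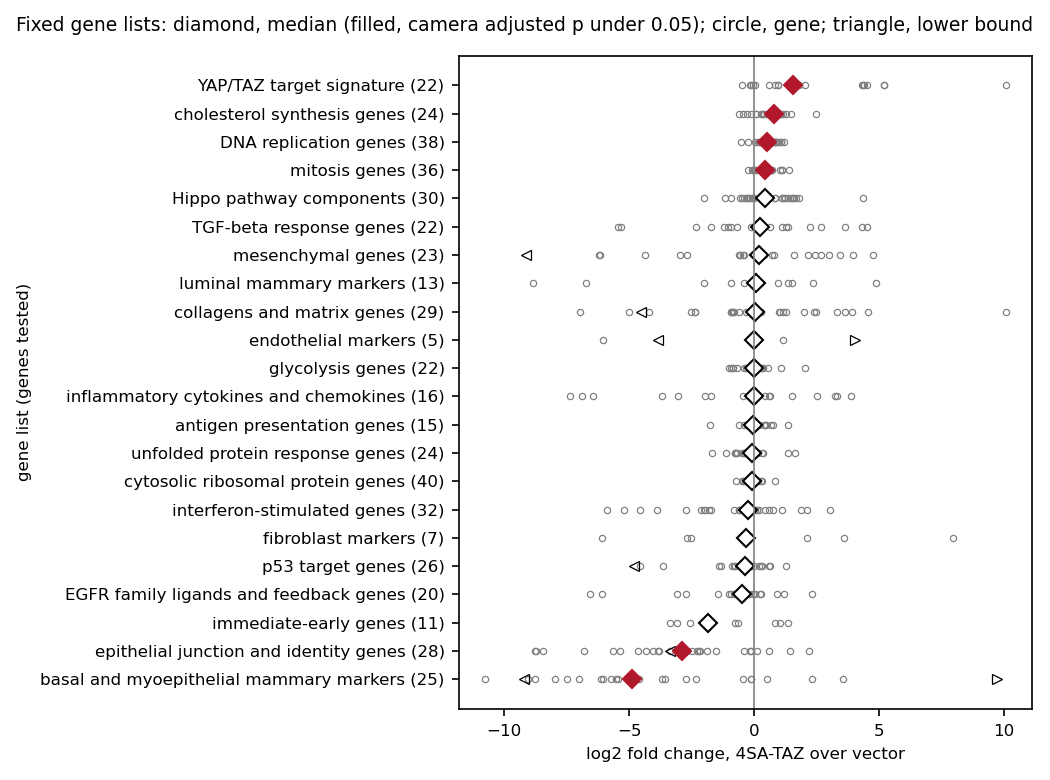
Log2 fold change (4SA-TAZ over vector) of each tested gene in the 22 tested lists, with triangles at the bound of genes at 0 counts in a group and a diamond at the list median, filled where camera gave an adjusted p under 0.05. The 6 filled lists are the YAP/TAZ signature, cholesterol synthesis, DNA replication and mitosis above 0, and the junction and basal lists below 0.

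Cholesterol synthesis genes rose as a group, with 9 of 24 tested members higher, 0 lower and 15 not passing, and 12 higher when adjusted over the list alone. The median log2 fold change was 0.78 (camera, adjusted p = 0.0016, and adjusted p = 0.738 with an estimated correlation and 0.0717 with fry). MVD rose 2.4-fold, from 83 ± 6.15 to 199 ± 13.6 CPM (SD, n = 2), IDI1 rose 2.23-fold, and ACAT2, which lies on chromosome 6, rose 5.55-fold. By edgeR's quasi-likelihood test the adjusted p was 0.00728 for MVD and 0.0111 for IDI1. Without 4SA-TAZ replicate 1 or 2 MVD rose 2.48-fold or 2.31-fold and IDI1 2.39-fold or 2.06-fold. Neither gene passed there, with the spread taken from the vector libraries alone.

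Mitosis genes were higher as a list, although the shifts were small. Of 36 tested members 5 rose, 0 fell and 31 did not pass, with 4 higher when adjusted over the list alone, and the median log2 fold change was 0.45 (camera, adjusted p = 3.1e-04, and adjusted p = 0.659 with an estimated correlation and 0.0701 with fry). The spindle checkpoint kinase gene TTK, on chromosome 6, rose 2.61-fold, CDC20 rose 2.18-fold from 308 ± 42.9 to 669 ± 0.919 CPM (SD, n = 2), and the kinetochore gene NDC80 rose 2.02-fold. Without 4SA-TAZ replicate 2 TTK, CDC20 and NDC80 rose 2.52-fold, 2.2-fold and 1.97-fold. Without 4SA-TAZ replicate 1 CDC20 and NDC80 rose 2.15-fold and 2.07-fold. None of these passed there, with the spread taken from the vector libraries alone. DNA replication genes had 0 of 38 tested members past the threshold with edgeR in either direction, also when adjusted over the list alone, 3 at an unadjusted p under 0.05, 2 with DESeq2 and 0 with limma-voom. Still, 36 had a positive log2 fold change, with a median of 0.52 (camera, adjusted p = 0.00376, and adjusted p = 0.989 with an estimated correlation and 0.476 with fry). CDC6 had 78.5 ± 35.7 CPM in vector and 166 ± 5.78 CPM in 4SA-TAZ, TYMS 52.5 ± 32 and 110 ± 7.11 CPM, and RFC4 51 ± 1.1 and 72.4 ± 10.3 CPM (SD, n = 2). Without vector replicate 1 the fitted rise of CDC6, TYMS and RFC4 was 1.6-fold, 1.46-fold and 1.45-fold. Without vector replicate 2 it was 3.08-fold, 3.63-fold and 1.39-fold. The list's median difference between vector replicate 1 and vector replicate 2 was -1.33 on the log2 scale, lower in replicate 1, and without vector replicate 1 camera gave an adjusted p of 0.765.

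EGFR ligands and feedback genes had 2 of 20 tested members higher, 6 lower and 12 not passing, with 2 and 8 when adjusted over the list alone. The list was not called (camera, adjusted p = 0.0592). By the same test its adjusted p was 0.0173 without vector replicate 1, 0.188 without vector replicate 2, 0.0228 with no filter, 0.0463 on limma-voom values and 0.0267 without chromosome 6 genes, and fry gave 0.0331. The ligand gene TGFA fell 67.6-fold from 28.6 ± 5.31 CPM (SD, n = 2) and the ERK phosphatase gene DUSP6 fell 6.61-fold, while the ligand gene HBEGF rose 5-fold. TGFA had 6 and 4 counts in the 4SA-TAZ libraries. Among p53 targets 1 of 26 tested members rose, 4 fell and 21 did not pass, the same as when adjusted over the list alone. The list was not called (camera, adjusted p = 0.0897). Between vector replicates 1 and 2 its median difference was 0.51 on the log2 scale, higher in replicate 1. By camera the list passed without vector replicate 2 but not without vector replicate 1. The death receptor gene FAS fell 23.8-fold, PHLDA3 fell 2.52-fold and SPATA18 was at least 28.1-fold lower, or 10.1-fold and 18-fold without 4SA-TAZ replicate 1 and 2. PHLDA3 fell 2.61-fold and 2.45-fold without 4SA-TAZ replicate 1 and 2. It did not pass there, with the spread taken from the vector libraries alone.

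Glycolysis genes had 1 of 22 tested members higher, 2 lower and 19 not passing, the same as when adjusted over the list alone (camera, adjusted p = 0.988). ENO2 rose 4.07-fold, or 6.48-fold without vector replicate 1, HK1 fell 2.01-fold and PFKM fell 1.8-fold. Without 4SA-TAZ replicate 1 ENO2 rose 3.74-fold, while HK1 and PFKM fell 2-fold and 1.84-fold. Without 4SA-TAZ replicate 2 HK1 and PFKM fell 2.03-fold and 1.76-fold. None of these passed there, with the spread taken from the vector libraries alone. Unfolded protein response genes had 1 of 24 tested members higher, 1 lower and 22 not passing, with 0 and 1 when adjusted over the list alone (camera, adjusted p = 0.868). VLDLR rose 3.1-fold, or 4.71-fold without vector replicate 1, and EDEM1 fell 2.17-fold. Without 4SA-TAZ replicate 1 and 2 VLDLR rose 3.23-fold and 3-fold, and EDEM1 fell 2.41-fold and 1.98-fold. Neither gene passed there, with the spread taken from the vector libraries alone. DDIT4 had 263 ± 163 CPM in vector and 80.9 ± 7.72 CPM in 4SA-TAZ (SD, n = 2, adjusted p = 0.0511 by edgeR's quasi-likelihood test). Its fitted level was 3.25-fold lower in 4SA-TAZ, or 1.82-fold and 4.71-fold lower without vector replicate 1 and 2.

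Interferon-stimulated genes had 3 of 32 tested members higher, 8 lower and 21 not passing, with 5 and 10 when adjusted over the list alone (camera, adjusted p = 0.095, or 0.0228 with no filter). By camera the list also passed without vector replicate 2, but not without vector replicate 1. BST2 fell 14.8-fold from 46 ± 3.64 CPM (SD, n = 2), OAS3 fell 4.39-fold and OASL fell 23.9-fold, or 41.2-fold without 4SA-TAZ replicate 1. OASL had 133 and 44 counts in the vector libraries and 4 and 1 in the 4SA-TAZ libraries. Inflammatory cytokines and chemokines had 5 of 16 higher, 7 lower and 4 not passing, the same as when adjusted over the list alone (camera, adjusted p = 0.868). The acute-phase gene SAA1 rose 14.7-fold, from 30.3 and 12.1 CPM in vector replicates 1 and 2 to 315 ± 9.66 CPM, or 26.1-fold without vector replicate 1. S100A8 and S100A9 fell from 7.74 ± 2.45 and 21.6 ± 6.16 CPM to 2 and 0 counts and to 2 and 1 counts in the 4SA-TAZ libraries. Of 15 tested antigen presentation genes, 10 of them on chromosome 6, 1 rose, 1 fell and 13 did not pass, and 0 passed when adjusted over the list alone (camera, adjusted p = 0.868). HLA-C rose 2.53-fold and HLA-F fell 3.37-fold (adjusted p = 0.0429 and 0.0425 by edgeR's quasi-likelihood test), and ERAP2 had 26 ± 2.5 CPM in vector and 17.1 ± 0.74 in 4SA-TAZ, with an adjusted p of 0.129. Without 4SA-TAZ replicate 1 and 2 HLA-C rose 2.35-fold and 2.72-fold, and HLA-F fell 3.48-fold and 3.28-fold. Neither gene passed there, with the spread taken from the vector libraries alone. The fitted level of ERAP2 was 1.41-fold and 1.64-fold lower in 4SA-TAZ without vector replicate 1 and 2.

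Among markers of other cell types, of 7 tested fibroblast markers 3 rose, 3 fell and 1 did not pass, the same as when adjusted over the list alone (camera, adjusted p = 0.895), and COL1A1, the most abundant, fell 5.69-fold from 30.1 ± 3.1 CPM (SD, n = 2). Of 5 tested endothelial markers 1 rose, 2 fell and 2 did not pass, with 2 and 2 when adjusted over the list alone (camera, adjusted p = 0.868), and ROBO4 had 9.08 ± 2.03 and 9.07 ± 0.394 CPM. Only 3 of 15 leukocyte markers passed the filter, too few for a list test, with 0 higher and 2 lower, or 3 lower when adjusted over the list alone. LAPTM5 had 118 CPM in vector replicate 1 and 1.38 CPM in vector replicate 2. It had 0.645 and 0.457 CPM in 4SA-TAZ replicates 1 and 2, and its adjusted p by edgeR's test was 0.0839. It was 103-fold lower in 4SA-TAZ with all libraries but 2.38-fold lower without vector replicate 1, so the difference rested mostly on that library. Of 11 tested immediate-early genes, which respond to growth signals and to handling, 0 rose, 4 fell and 7 did not pass, with 2 and 7 when adjusted over the list alone (camera, adjusted p = 0.0897, or 0.0374 without vector replicate 2 and 0.0228 with no filter). EGR1 fell 8.52-fold, with 426 ± 407 CPM in vector and 50 ± 0.624 CPM in 4SA-TAZ (SD, n = 2), or 2.77-fold and 14.5-fold without vector replicate 1 and 2. Cytosolic ribosomal protein genes had 1 of 40 higher, 0 lower and 39 not passing, with 0 when adjusted over the list alone (camera, adjusted p = 0.643), and RPS2 had 2955 ± 654 and 2733 ± 41.3 CPM. The list's median difference between vector replicates 1 and 2 was 0.30 on the log2 scale, higher in replicate 1. RPS2, with 3418 and 2493 CPM in vector replicates 1 and 2, had an adjusted p of 0.776 by edgeR's quasi-likelihood test.

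Across the lists, 6 of the 22 tested were called by camera with the preset correlation, 4 higher and 2 lower, and 0 of the 6 were called with an estimated correlation, where 3 lists had an unadjusted p under 0.05. The YAP/TAZ list had an estimated correlation of 0.0138, near the preset 0.01. By camera its unadjusted p was 6.4e-08 with the preset and 0.0346 with the estimated correlation, so its loss came largely from the 2 residual degrees of freedom. Estimated correlations of the other called lists ranged from 0.0423 (junction) to 0.83 (DNA replication). For cholesterol synthesis, mitosis and DNA replication genes they were 0.197, 0.124 and 0.83. With these, camera gave unadjusted p of 0.235, 0.18 and 0.565. As fry did not call these lists either, their calls rest on the preset correlation. The self-contained test fry called 4 lists: the YAP/TAZ signature and the junction and basal lists (adjusted p = 0.00839 each), and the EGFR list (adjusted p = 0.0331). Without vector replicate 2, 10 lists were called.

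Genes on chromosome 6 were higher in 4SA-TAZ as a chromosome, a pattern first seen in these data. The median log2 fold change of its 672 tested genes was 0.89, or 1.85-fold, and 79.9% had a positive value. The medians of the other 22 chromosomes lay between -0.25 and 0.14. On chromosome 6, 268 genes rose and 42 fell by edgeR's quasi-likelihood test, and 39.9% of its genes rose against 6.87% on the other chromosomes. With the genes of chromosome 6 left out of the count, 2307 genes changed, 909 higher and 1398 lower.

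**Figure D4:**
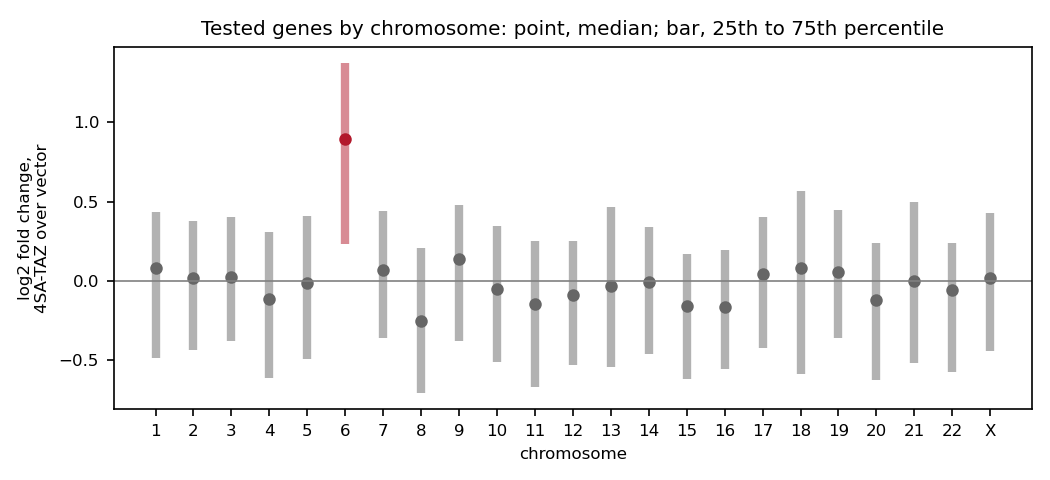
Log2 fold change (4SA-TAZ over vector) of tested genes on each chromosome, as the median (point) and the 25th to 75th percentile (bar). Chromosome 6 had a median of 0.89, and the other 22 chromosomes lay between -0.25 and 0.14.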

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

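The alternatives without chromosome 6 genes and without ribosomal RNA gene models were chosen after the data were examined, and all others before. The count of 2617 changed genes was 3944 with no filter and ranged from 1314 to 9029 when one library was left out, where the lone library is assumed to vary like the other group. It stayed within 1.5 times under the other settings, from 1835 with a test of change over 1.5-fold to 3253 with the replicate block. No gene among the 2617 had the opposite sign in any setting where it was tested. Without chromosome 6 genes it was 2185 (891 higher, 1294 lower) and without ribosomal RNA gene models 2628. The labels do not say what a shared replicate number marks, and samples were not taken as paired. The replicate differences of the 2 groups correlated at 0.141 across genes, and with the replicate block 1495 genes were higher and 1758 lower. WWTR1 (log2 fold change 0.89) passed the threshold with no filter (0.90), with DESeq2's Wald test (0.88) and with the replicate block (0.92, adjusted p = 0.0227 by edgeR), and ranged from 0.61 to 1.23 with a library left out. The cause was not tested. Of the fixed lists 6 were called, against 0 with an estimated correlation, 10 with no filter and 6 to 10 with a library left out. For the YAP/TAZ signature the adjusted p was 0.346 with an estimated correlation and 1.8e-08 to 1.1e-05 with a library left out. Scaling moved the median of all genes by at most -0.045 on the log2 scale.

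Of 1252 alternative values of 74 other named genes, 1174 kept direction and side of the threshold, 41 lost the call, 28 gained it and 9 reversed. The reversals were of genes that were not called. ROBO4 turned to -0.0053 with DESeq2 size factors, -0.033 with library size only, -0.036 with upper quartile, -0.0022 with the stricter filter, -0.0046 with DESeq2's Wald test and -0.021 without ribosomal RNA gene models. With a library left out ROBO4 ranged from -0.21 (without vector replicate 1) to 0.24 and was -0.065 without 4SA-TAZ replicate 1, and RPS2 ranged from -0.34 to 0.13 (the latter without vector replicate 1). Of 355 values of the other 21 lists, 308 were unchanged in this sense, 9 lost and 14 gained the call, and 24 reversed, none in a called list. Their adjusted p in the reversed direction was 0.117 with fry for mesenchymal genes. For luminal markers it was 0.188 with fry, 0.887 with the stricter filter, 0.945 after thinning, 0.87 without vector replicate 2 and 0.935 without 4SA-TAZ replicate 1. Cytokines gave 0.99 after thinning, and antigen presentation 0.973 with fry and 0.745 without vector replicate 2, within 0.273 to 0.823 over the libraries left out. Glycolysis genes gave 0.839 with no filter, 0.97 with the replicate block, 0.887 without chromosome 6 genes, 0.745 without vector replicate 2, and 0.935 and 0.869 without 4SA-TAZ replicate 1 and 2. The unfolded protein response list gave 0.236 without vector replicate 1 and 0.935 without 4SA-TAZ replicate 1, within 0.0732 to 0.935. Fibroblast markers gave 0.407 with no filter, 0.745 without vector replicate 2 and 0.981 without 4SA-TAZ replicate 1. Endothelial markers gave 0.389 with no filter, 0.887 without chromosome 6 genes and 0.807 without vector replicate 2, within 0.179 to 0.935. Ribosomal protein genes gave 0.613 without vector replicate 1, within 0.00853 to 0.935. The cause was not tested. In simulated data of this size 4 of 50 genes changed 2-fold were recovered, so a gene changed 2-fold may be missed. The simulation changed far fewer genes than were called here and gave both groups the same spread, so its recovery need not hold for these data. Some genes with smaller folds, such as PFKM at 1.8-fold, were called here.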

Other observations

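All tests in this part were chosen after the result was seen, except that the test of library depth was written before its value was known, and those of an unrelated line and of growth state were widened after their first values were seen. Gene families defined by the root of their symbols were tested with camera after the data were examined. A first set of 57 families gave 10 calls. After that result was seen, 5 roots were narrowed, 4 of which had also taken unrelated tested genes, and 1 was dropped, which gave 56 families and 11 calls, and 0 were called with an estimated correlation under either set. With an estimated correlation 1 family had an unadjusted p under 0.05 in each set, and the smallest adjusted p of the revised set was 0.593. The families described next were called under both sets unless said otherwise, with adjusted p from the revised set, and their genes were chosen after their values were seen.

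Pregnancy-specific glycoprotein genes, a cluster on chromosome 19, rose in 6 of 6 tested members (camera, adjusted p = 2.2e-06), with a median log2 fold change of 9.10, or 6.15 with genes at 0 in vector at their bounds. PSG4 had 0.186 ± 0.195 CPM in vector and 21.2 ± 2.6 CPM in 4SA-TAZ (SD, n = 2), and PSG5 was at least 105-fold higher, or 38.9-fold and 65.6-fold without vector replicate 1 and 2. These genes are close copies, and which copy a read came from is uncertain. Genes with the root ADAMTS had 7 of 12 members higher and 0 lower (camera, adjusted p = 0.0177). The root takes in ADAMTS-like genes as well as the ADAMTS proteases, and ADAMTSL1 and ADAMTSL4 were among the 7. ADAMTS1 rose from 3.34 ± 1.46 to 310 ± 43.3 CPM and ADAMTS12 from 0.363 ± 0.173 to 151 ± 9.13 CPM. HOX genes had 6 of 15 members higher and 0 lower (camera, adjusted p = 0.00855). S100A genes had 8 of 11 members lower and 0 higher (camera, adjusted p = 7.1e-06), and S100A2 fell from 1587 ± 509 to 36.3 ± 0.935 CPM. Clustered protocadherin genes had 7 of 8 lower and 0 higher by the same test (adjusted p = 7.1e-06), though their models overlap and share exons. The other families called lower were histones (6 of 25 members lower, 16 of the 25 on chromosome 6), FAM83 genes (3 of 6), AKR genes (4 of 7), keratins (10 of 18 lower and 5 higher) and laminins (5 of 8 with the narrowed root). Interleukin genes and their receptors (8 of 30 lower and 3 higher) were called only with the narrowed root (camera, adjusted p = 0.0287).

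The rise of chromosome 6 genes was seen along its length. In 14 of 14 windows of 10 Mb with at least 20 genes the median lay above a value (0.34) exceeded by 6 of 235 windows on other chromosomes, and the windows ranged from 0.35 to 1.2, which argues against regulation of part of the chromosome as the whole cause. A correction for GC content, length and abundance fitted on the other chromosomes left the median at 0.97, against 0.89 before, which argues against those biases. Relative to the other chromosomes the libraries lay at -0.42 and -0.49 in vector and 0.46 and 0.45 in 4SA-TAZ, a gap of 0.87 between the nearest libraries. A whole-chromosome difference in copy number between the cells of the groups is a candidate explanation, found and tested on the same data, and no DNA measurement was used here.

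Some genes were at 0 counts in both libraries of a group and abundant in the other: 45 were at 0 in vector and 51 at 0 in 4SA-TAZ, with at least 100 counts in the other group. Between duplicates, 3 genes went from 0 to at least 50 counts in vector and 0 did in 4SA-TAZ. For an unrelated aneuploid cell line in one group, several chromosomes other than 6 should be shifted. Whole-chromosome medians were beyond 0.3 either way in 0 of the 22, but shorter runs of windows were lower, as given below. Such a line was therefore not decided, and no read sequence was used here to identify the cells. Activated TAZ acting in the cells, for which 14 signature members rose and 0 fell, is another candidate. So is a subline that differed before transfection, for which chromosome 6 had a median of 0.89. TAZ and subline cannot be told apart, because no group holds the transgene in other cells. More than 1 of them may contribute.

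The vector duplicates differed more than the 4SA-TAZ duplicates. Thinned to 8991524 counts each, they still held 1380 genes over 2-fold apart against 14, which argues against depth. Gene models within ribosomal RNA loci took 0.486% and 1.82% of counts in the vector libraries, but the 4SA-TAZ libraries also differed by 1.26 percentage points with few genes apart, which argues against ribosomal carry-over. A difference in growth state was not decided: the median DNA replication gene was -1.33 log2 units in vector replicate 1 relative to replicate 2, at percentile 0 of 10000 random lists matched on abundance, but the median mitosis gene was -0.16, at percentile 36.55. Other lists lay far out on the upper side, with unfolded protein response and ribosomal protein genes at percentile 100, immediate-early genes at 99.99 and p53 targets at 99.96. Lists also lay far out between the 4SA-TAZ duplicates, with smaller medians: the unfolded protein response list was at percentile 0.09 with a median of -0.13, against 0.73 in vector. Such a percentile alone does not set the vector duplicates apart. Among genes chosen after their values were seen, RRM2 had 77.5 and 304 CPM and TSC22D3, a glucocorticoid-responsive gene, 989 and 72.1 CPM in vector replicates 1 and 2.

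Outside chromosome 6, the window with the highest median was at 20000001 to 30000000 on chromosome 19, at 1.04, where 12 of 22 genes rose and 0 fell. ZNF91, a zinc finger gene in it chosen after its values were seen, had 0 counts in vector and 11.2 ± 1.18 CPM in 4SA-TAZ (SD, n = 2), at least 124-fold higher, or 46.2-fold and 77.8-fold without vector replicate 1 and 2. Below -0.34 lay 13 of the 235 windows, the lowest at 90000001 to 100000000 on chromosome 11, at -0.54. With the next 3 windows, at -0.45, -0.28 and -0.48, it formed a run of 174 tested genes with a median of -0.43, of which 40 fell and 9 rose, and which holds YAP1 and AMOTL1. A run of 3 windows at the start of chromosome 20 had a median of -0.28 over 122 genes, and the cause of these shifts was not tested.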
